A study of Mus musculus with 4 samples.

How the data were processed

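Droplet single-cell RNA sequencing (10x Genomics) was carried out on mouse retina at embryonic day 14.5, with 2 libraries from wild-type retina (WT) and 2 from retina lacking the remote enhancer of Atoh7 (RE_KO). The deposited matrices hold raw counts, namely the number of unique molecular identifiers (UMIs) per gene and cell, with 1 matrix per library. Per the file headers they were written by Cell Ranger 5.0.1, and the labels give the mm10 build. No normalisation had been applied, and all barcodes of each matrix were read. The matrices list 32285 gene identifiers, of which 32235 (99.8%) had coordinates in GENCODE mouse release M21. Counting intervals are exact (Clopper-Pearson) at 95% and cover counting error only.

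Cells were kept with at least 1000 detected genes and at most 10% mitochondrial UMIs. Scrublet, run per library in scanpy 1.11.5, marked 0 cells in 3 libraries and 2 cells in RE_KO replicate 2. Because this was under 0.5%, the cells with the highest doublet scores were removed at 0.8% per 1000 cells. The 4 libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (igraph 0.11.9). Atoh7, all marker and list genes, Xist, Tsix, Y-linked, mitochondrial, ribosomal and haemoglobin genes were left out of the variable genes. Clusters were named from marker sets of 13 classes, written down beforehand, and each name ends in "-like".

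A cluster kept its name when its mean marker score reached 0.9 and led the next class by 0.3, and when 3 markers were detected. Clusters whose 10 leading genes held more markers of another class stayed unnamed, as did clusters of low UMI count with no own marker among those genes. These naming thresholds were set after the data were seen. Of 27 clusters, 17 were named and 10 stayed unnamed. The unnamed clusters held 39.6% ± 11.3 of the kept cells in WT and 28.1% ± 9.56 in RE_KO (mean ± SD, n = 2 libraries each). A low marker score was the reason for 7 of them.

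Counts were summed per library over all kept cells and over each of 5 neural retinal classes, each of which had at least 20 cells in every library. RE_KO was compared with WT by edgeR 4.0.16 quasi-likelihood tests with robust dispersion, TMM factors and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression values are counts-per-million (CPM) on TMM-adjusted library sizes. Class shares were tested by the same method on the number of cells of each class, with the total of neural retinal cells as offset and adjustment over the 5 classes. A model over RGC-like and progenitor-like cells, with library as block, tested whether the genotype effect differed between these classes. RGC stands for retinal ganglion cell. In all cells and in 3 classes, 19 gene lists were tested by camera (limma 3.58.1) with a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. Lists needed at least 5 tested genes. DESeq2 1.42.0 served as the other tool, under R 4.3.3 and Python 3.11.15.

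The tests, the 19 lists, the markers, the filters and the rule for naming genes were fixed before the data were examined. The rule names Atoh7 first. It then takes from each fit the 6 largest rises and 6 largest falls among genes past the threshold that average at least 20 CPM and have both RE_KO libraries on the same side of both WT libraries. Predicted, mitochondrial, ribosomal, haemoglobin and sex-linked genes were not named by this part. From each list described in a fit, the 4 members with the smallest adjusted p were named, and from the interaction fit the 4 largest differences each way. Genes that make up a count of 5 or fewer are named outside this rule, after their values were seen.

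With 2 libraries per genotype, an exact permutation test cannot give a two-sided p under 0.333, so none is reported and the tests rest on the spread pooled across genes or classes. The p-values measure only the spread between these samples, since the labels do not say whether the replicates came from separate animals or litters. On data simulated at this size, the edgeR test recovered 89.6% of 2-fold and 23.9% of 1.5-fold changes in RGC-like cells, and 2.07% of its calls were wrong. In the model of the difference between classes, 34.3% of 2-fold and all of the 4-fold differences were recovered, and 5.15% of calls were wrong. For shares, 8% of 100 simulations with a spread of 10% gave a false call, and a class reduced to 1/2 was called in 91%. Genes were drawn independently, with a dispersion that followed expression level or, for the difference, was fixed. The changed genes were drawn from those of at least 20 CPM, in both classes for the difference. The recovered percentages therefore do not cover genes below that level. No simulated library stood apart from the rest, so these rates may overstate what was recovered here. All 4-fold changes simulated in neurogenic-progenitor-like cells were recovered, yet edgeR did not call the fall of Atoh7 there (log2 fold change -2.46, adjusted p = 0.0719).

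For shares of cells with an Atoh7 UMI, each cell was thinned to 2500 UMIs, and cells with fewer were left out of those shares. The alternatives tried were DESeq2, no TMM, TMM over classes, no filter on low counts, replicate number as a block, equal depth, each library left out, a stricter cell filter (1500 genes, 5% mitochondrial UMIs), no doublet removal, Leiden resolution 2, list genes kept in the clustering, libraries clustered alone and another denominator. Others were chosen after seeing the data: leaving out cells over 25000 UMIs, clustering without any gene called in a class, crossing the pairs, and shares without thinning.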

Results

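Retinal cells of WT and RE_KO mouse embryos were profiled to ask what loss of the remote enhancer of Atoh7 does to the gene it serves and to the classes of retinal neurons formed at this stage. Atoh7 encodes a basic helix-loop-helix transcription factor that retinal progenitors need to form retinal ganglion cells. The WT libraries held 10240 barcodes with 104746587 UMIs (replicate 1) and 10873 barcodes with 131800569 (replicate 2). The RE_KO libraries held 11183 barcodes with 104868394 UMIs and 12436 barcodes with 118565445. After filtering and doublet removal, 6071 and 8024 WT cells and 6303 and 7924 RE_KO cells remained, with median depths of 7842, 5573, 6732 and 6729.5 UMIs in that order. Neural retinal classes took in 17105 of the 28322 cells.

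The libraries within each genotype differed by far more than counting noise and were kept as separate samples, though this does not show that they were prepared separately. Chi-square per degree of freedom was 56.6 between the WT libraries and 469 between the RE_KO libraries. RE_KO replicate 1 lay at 105 from WT replicate 1 and 84.0 from WT replicate 2, closer to both than to RE_KO replicate 2. Between RE_KO replicate 2 and the WT libraries the values were 374 and 543. The median absolute log2 ratio per gene was 0.224 to 0.262 for pairs with RE_KO replicate 2. It was 0.102 to 0.170 for the remaining pairs, so the distance of this library was not confined to a few genes. RE_KO replicate 2 stood apart from the other 3 libraries in its replication-dependent histone transcripts, whose median log2 ratio to them was -1.81 in progenitor-like cells, with 58 of 61 genes lower. In RE_KO replicate 2, cluster c1, led by histone genes, held 0.878% of the progenitor-like cells (95% interval 0.557 to 1.31), against 41.3% to 42.3% in the other libraries. There, cluster c4, led by mitotic genes, held 50.2% (48.3 to 52.2), against 7.45% to 10.6%.

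Atoh7 (ENSMUSG00000036816, a protein-coding gene on chromosome 10, positions 63099651 to 63101279, plus strand) was far below WT in every class of RE_KO cells. In neurogenic-progenitor-like cells, where it was highest, it measured 4203 and 4181 CPM in WT and 701 and 826 in RE_KO (log2 fold change -2.46, SE 0.25, n = 2 libraries each). In RGC-like cells it fell from 373 and 395 CPM to 38.8 and 36.6 (log2 fold change -3.35, SE 0.16, adjusted p = 0.0012), where the RE_KO values lie at the level of free RNA in erythroid-like and microglia/macrophage-like cells (131 and 325 CPM in WT, 29.6 and 76.1 in RE_KO). It also fell in photoreceptor-precursor-like cells, from 1140 and 1114 CPM to 112 and 133 (log2 fold change -3.20, SE 0.23, adjusted p = 1.64e-04). Amacrine/horizontal-like cells went from 265 and 408 CPM to 83.6 and 66.3 (log2 fold change -2.17, SE 0.23, adjusted p = 0.0191), near that level in RE_KO as well.

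**Figure D1:**
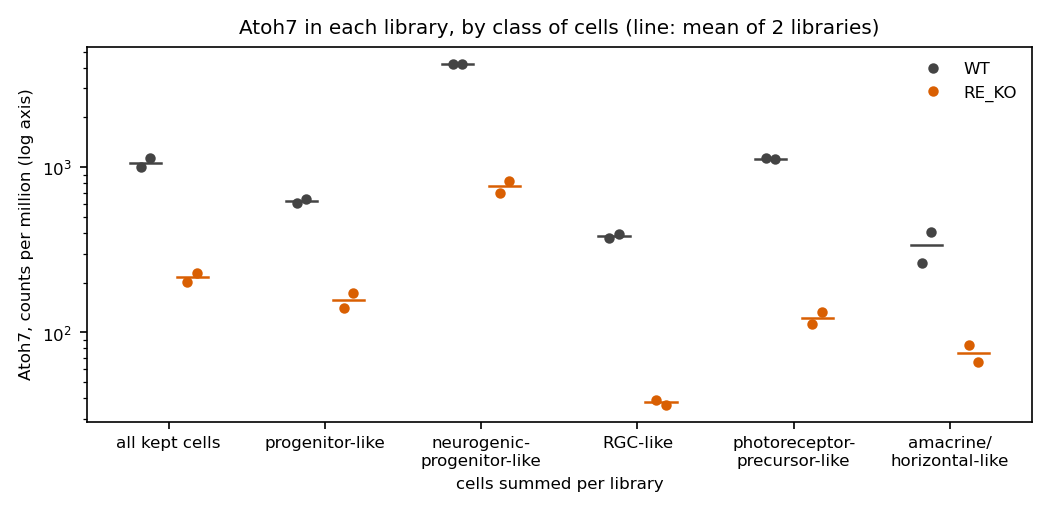
Atoh7 level (CPM, log axis) in each library, summed over all kept cells and over each neural retinal class. Dots are libraries and lines are means of 2 libraries. WT neurogenic-progenitor-like cells lie near 4203 and 4181 CPM, and every RE_KO library lies below both WT libraries in every class.

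The edgeR test did not call Atoh7 in neurogenic-progenitor-like cells (adjusted p = 0.0719), in progenitor-like cells (608 and 637 CPM in WT, 141 and 173 in RE_KO, log2 fold change -1.99, SE 0.18, adjusted p = 0.277) or over all kept cells (1002 and 1130 CPM, then 202 and 228, log2 fold change -2.31, SE 0.19, adjusted p = 0.113). DESeq2 called it in each (adjusted p = 2.78e-29, 1.20e-23 and 1.34e-46). Dropping RE_KO replicate 1 or RE_KO replicate 2 moved edgeR's adjusted p in neurogenic-progenitor-like cells to 6.15e-16 and 1.07e-19, while dropping WT replicate 1 or WT replicate 2 moved it to 0.28 and 0.41. Over all cells these removals gave 5.95e-06, 2.17e-05, 0.833 and 0.51. In progenitor-like cells they gave 2.95e-14, 4.83e-17, 0.963 and 1. The call in amacrine/horizontal-like cells was lost without RE_KO replicate 2 (log2 fold change -2.00, adjusted p = 0.0607).

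Cells with an Atoh7 UMI, at 2500 UMIs per cell, made up 96.9% ± 0.54 of neurogenic-progenitor-like cells in WT and 63.0% ± 2.09 in RE_KO (mean ± SD, n = 2 libraries each). Photoreceptor-precursor-like cells showed 76.1% ± 2.21 and 19.8% ± 3.07, and progenitor-like cells 37.4% ± 1.37 and 14.8% ± 2.88. For RGC-like cells the shares were 41.4% ± 5.08 and 7.69% ± 0.313, and for amacrine/horizontal-like cells 34.2% ± 1.35 and 10.5% ± 0.397. As background, microglia/macrophage-like cells, which should lack Atoh7, showed 24.2% ± 8.89 in WT and 5.95% ± 0.858 in RE_KO, and erythroid-like cells 25.7% ± 13.8 and 7.74% ± 4.21. The RE_KO values in RGC-like and amacrine/horizontal-like cells lay within the spread of these backgrounds, so the thinned shares do not show expression there. Without thinning, RGC-like cells of RE_KO (22.9% and 24.4%) lay above microglia/macrophage-like cells (11.7% and 12.2%). They lay within the erythroid-like intervals (5.43 to 28.5 and 15.3 to 50.8). RGC-like cells were also deeper, at medians of 14895.5 and 11201 UMIs, so free RNA is not settled for them in RE_KO. Microglia/macrophage-like cells showed 17.9% (95% interval 10.2 to 28.3) in WT replicate 1 and 30.5% (21.5 to 40.8) in WT replicate 2. Amacrine/horizontal-like cells showed 35.1% (29.5 to 41.0) and 33.2% (27.3 to 39.5). They lay above that background in WT replicate 1 alone, and the erythroid-like spread took them in, so free RNA is not settled for them in WT. The shares in progenitor-like cells of both genotypes, in RGC-like cells of WT and in photoreceptor-precursor-like cells of RE_KO lay within the intervals of the few erythroid-like cells of WT replicate 2 (35.5%, 95% interval 19.2 to 54.6) and RE_KO replicate 2 (10.7%, 2.27 to 28.2). By those of WT replicate 1 (16%, 4.54 to 36.1) and RE_KO replicate 1 (4.76%, 0.582 to 16.2) they lay above, except for progenitor-like cells of RE_KO (12.7%), so erythroid-like cells do not settle free RNA for them. Microglia/macrophage-like cells, more numerous, showed 6.56% (3.43 to 11.2) and 5.34% (2.18 to 10.7) in RE_KO. Compared with these cells of the same library, RGC-like cells of WT (37.8% and 45.0%) and photoreceptor-precursor-like cells of RE_KO (17.6% and 21.9%) lay above in each. For progenitor-like cells the intervals overlapped in WT replicate 2 and RE_KO replicate 1. Median depth per library was 5350 to 8103 UMIs in neurogenic-progenitor-like, 4554 to 8353 in microglia/macrophage-like and 7610 to 12189.5 in erythroid-like cells. All non-neural classes, ciliary-margin-like and pigment-epithelium-like cells included, carried 563 and 913 Atoh7 UMIs in WT and 153 and 242 in RE_KO (log2 ratio -2.17). Erythroid-like and microglia/macrophage-like cells alone carried 132 and 405 (131 and 325 CPM) in WT and 69 and 95 (29.6 and 76.1 CPM) in RE_KO, so the free RNA was lower with the gene itself. Without thinning, the neurogenic-progenitor-like share in RE_KO was 74.6% ± 1.64.

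The makeup of the neural retina was compared next. RGC-like cells fell from 37.4% ± 3.89 of neural retinal cells in WT to 21.2% ± 2.43 in RE_KO (log2 fold change -0.82, SE 0.15, adjusted p = 0.00134, n = 2 libraries each). Progenitor-like cells rose from 31.4% ± 2.11 to 44.9% ± 0.176 (log2 fold change 0.51, SE 0.15, adjusted p = 0.0146). Photoreceptor-precursor-like cells rose from 4.59% ± 0.132 to 6.59% ± 0.747 (log2 fold change 0.51, SE 0.17, adjusted p = 0.0237). The neurogenic-progenitor-like class held 17.99% ± 0.294 and 18.2% ± 0.94 (log2 fold change 0.01, SE 0.15, adjusted p = 0.924), and the amacrine/horizontal-like class 8.58% ± 2.21 and 9.18% ± 0.921 (log2 fold change 0.09, SE 0.16, adjusted p = 0.725). The shares of the 5 classes add up to a fixed total, so a lower RGC-like share by itself raises the others. The rises and the level shares are therefore not independent of that fall. Shares among the classes without RGC-like cells were not tested.

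**Figure D2:**
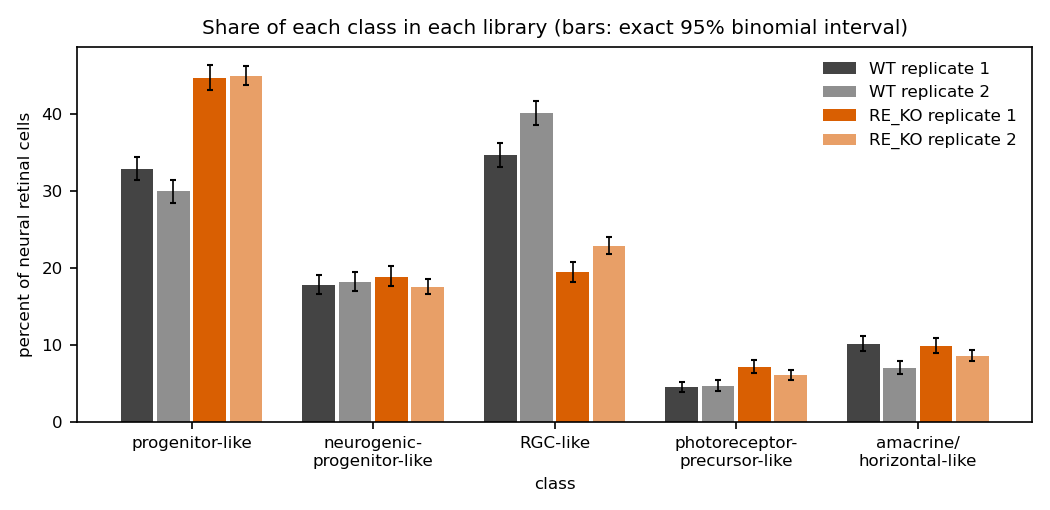
Percent of neural retinal cells in each class, per library, with bars for exact 95% binomial intervals (counting error only). RGC-like cells average 37.4% in WT and 21.2% in RE_KO, and progenitor-like cells 31.4% and 44.9%.

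These shares leave out the unnamed clusters, and over all kept cells none of the 5 passed (RGC-like log2 fold change -0.57, adjusted p = 0.163; progenitor-like 0.73 and photoreceptor-precursor-like 0.74, each with adjusted p = 0.115). The RGC-like call was also lost without WT replicate 2 (-0.71, adjusted p = 0.0682), without RE_KO replicate 1 (-0.71, adjusted p = 0.119) and with libraries clustered alone (-0.75, adjusted p = 0.221). Without WT replicate 2, RE_KO replicate 1 or RE_KO replicate 2 the progenitor-like call was lost, at adjusted p of 0.0682, 0.142 and 0.101, and it was lost with libraries clustered alone (log2 fold change 0.22, adjusted p = 0.596). The photoreceptor-precursor-like call was lost whichever library was removed (log2 fold change 0.40 to 0.63, adjusted p 0.101 to 0.247) and under 6 other alternatives, with 0.06 at the stricter cell filter. Within the RGC-like class, cluster c11 held 32.1% of the cells in WT replicate 2 (95% interval 29.8 to 34.5) and 7.05% to 14.4% in the other libraries. The unnamed clusters weigh on the shares of all kept cells. Cluster c5, of low UMI count, scored best as RGC-like (1.12) and held 8.68% and 7.38% of kept cells in WT. In RE_KO it held 4.93% and 2.25%. Cluster c15, with haemoglobin genes among its leading genes, held 22.5% of WT replicate 2 and 2.88% to 6.34% of the other libraries. Cluster c9, which scored best as progenitor-like (0.81), was higher in RE_KO.

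Over all kept cells, the question was which genes differed when class makeup and change within classes add up. Robo3, a receptor of the Roundabout family in axon guidance, rose from 1.07 and 0.84 CPM in WT to 10.9 and 12.4 in RE_KO (log2 fold change 3.62, SE 0.18, adjusted p = 0.0306, n = 2 libraries each). Gng4, a G protein gamma subunit, fell from 7.59 and 6.92 CPM to 0.90 and 0.80 (log2 fold change -3.10, SE 0.16). Rec8, a meiotic cohesin subunit, fell from 1.89 and 1.92 CPM to 0.11 and 0.10 (log2 fold change -4.12, SE 0.24). Ccdc7a rose from 0.26 and 0.24 CPM to 3.10 and 3.89 (log2 fold change 3.82, SE 0.23). These 4 genes average under 20 CPM, fall outside the naming rule and were chosen after their values were seen.

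They were the 4 genes called of 17639 tested by edgeR, while 2493 had an unadjusted p under 0.05 and DESeq2 called 504. Without WT replicate 1 or WT replicate 2 the edgeR count was 0, with 753 and 872 at an unadjusted p under 0.05, and without RE_KO replicate 1 or RE_KO replicate 2 it was 4711 and 1449. With cells over 25000 UMIs left out it was also 0, with 2204 at an unadjusted p under 0.05. DESeq2 was run on all libraries and kept cells alone.

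Ganglion cell genes measured lower over all cells. Transcription factors of RGC fate tested lower as a list (camera adjusted p = 1.77e-15, median log2 fold change -0.59), and adjusted over the list alone 17 of 27 passed, all lower. The call did not hold with the correlation estimated (adjusted p = 0.294 with an estimated correlation), and over all genes tested 0 members passed. Its leading members were Eya2, a transcriptional cofactor (log2 fold change -1.06, SE 0.13), the POU factor Pou6f2 (-0.99, SE 0.15) and the Iroquois factors Irx5 (-1.31, SE 0.20) and Irx2 (-0.83, SE 0.12). Axon growth and guidance genes also tested lower (camera adjusted p = 9.96e-15; adjusted p = 0.448 with an estimated correlation), with 17 of 41 lower adjusted over the list alone. Islr2 (-1.12, SE 0.12), the adhesion molecule Dscam (-0.85, SE 0.10), the netrin receptor Dcc (-0.75, SE 0.11) and the actin-binding Ablim1 (-0.72, SE 0.11) led it. Synapse and excitability genes of RGCs followed (camera adjusted p = 2.23e-07; adjusted p = 0.467 with an estimated correlation; 6 of 19 lower adjusted over the list alone). Among them were the sodium channel Scn3a (-0.80, SE 0.10), calretinin (Calb2, -0.79, SE 0.12), Syt4 (-0.77, SE 0.13) and the neuronal RNA-binding protein Elavl4 (-0.76, SE 0.15).

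Genes of neurogenic progenitors, photoreceptors and amacrine cells measured higher over all cells. The neurogenic progenitor list (camera adjusted p = 3.65e-07; adjusted p = 0.294 with an estimated correlation) had 10 higher and 1 lower of 23 adjusted over the list alone, among them the proneural factors Neurog2 (log2 fold change 0.83, SE 0.13) and Neurog1 (1.18, SE 0.20), Olig2 (0.63, SE 0.09) and the somatostatin receptor Sstr2 (0.84, SE 0.14). Cone and rod precursor genes (camera adjusted p = 2.11e-07; adjusted p = 0.467 with an estimated correlation) had 5 higher and 1 lower of 20, with the phototransduction genes Gnat2 (1.21, SE 0.15) and Gnb3 (1.10, SE 0.11), Rbp3 (0.97, SE 0.13) and, lower, the nuclear receptor Rxrg (-0.50, SE 0.10). The amacrine and horizontal list (camera adjusted p = 9.01e-09; adjusted p = 0.467 with an estimated correlation) had 10 of 21 higher, with the GABA transporter Slc32a1 (1.24, SE 0.16), Tfap2c (1.04, SE 0.16), Neurod2 (2.88, SE 0.58, at most 0.32 CPM) and Ptf1a (0.46, SE 0.10). Progenitor maintenance and Notch genes (camera adjusted p = 1.14e-04; adjusted p = 0.467 with an estimated correlation) had 4 of 24 higher: Heyl (0.84, SE 0.12), Hes5 (1.06, SE 0.19), Vsx2 (0.58, SE 0.14) and Lfng (0.43, SE 0.10). None of these members passed over all genes tested, where adjusted p ran from 0.129 upwards for every list member named.

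Among lists of non-neural markers, microglia and macrophage genes tested higher over all cells (camera adjusted p = 1.63e-11; adjusted p = 0.467 with an estimated correlation; 5 of 14 higher adjusted over the list alone), with the complement genes C1qb (log2 fold change 1.12, SE 0.22) and C1qc (1.18, SE 0.24), Trem2 (1.43, SE 0.22) and Lyz2 (0.98, SE 0.12). Without RE_KO replicate 1 that list's median went from 0.97 to 0.20, and without RE_KO replicate 2 it was 1.496, with the call kept each time. The class named microglia/macrophage-like joins cluster c20 (202 cells), led by Cx3cr1, Csf1r and C1qb, and cluster c0 (395 cells), where the neutrophil genes S100a9, S100a8, Ngp and Camp stand beside Pf4, Lyz2 and Mrc1, so its cells are not all microglia or macrophages. It made up 1.62% ± 0.0865 of kept cells in WT and 2.67% ± 0.848 in RE_KO. The pigment epithelium and lens list (camera adjusted p = 0.0129; adjusted p = 0.526 with an estimated correlation; 0 of 15 adjusted over the list alone) included the lens gene Mip (3.39, SE 2.07), Tyrp1 (0.57, SE 0.28), Mlana (0.43, SE 0.21) and Ttr (-0.66, SE 0.38). Ttr was at -0.05 without WT replicate 1 and -1.09 without WT replicate 2. RE_KO replicate 1 set the value of the list: Mip measured 16.7 CPM there against 0.13 to 1.57 in the other libraries, and without this library the list's median was -0.11. The G2 and M phase list was called (adjusted p = 0.0127; adjusted p = 0.621 with an estimated correlation), and the S phase list was not (adjusted p = 0.0677).

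Of 19 lists, 10 were called over all cells by camera, 7 higher and 3 lower. With an estimated correlation 0 were called, by fry in one direction 0, and by its test of change in either direction 10. Not called were the Hedgehog target (adjusted p = 0.363), p53 and apoptosis (0.0655), dissociation stress (0.0655), hypoxia and glycolysis (0.33) and Atoh7-neighbour (0.515) lists. Among lists that were not called, these had a median and mean of opposite sign: erythroid (0.36 and -0.0061, adjusted p = 0.425), vascular and mesenchyme (0.029 and -0.028, adjusted p = 0.401, tested higher) and optic stalk, astrocyte and ciliary margin (0.059 and -0.095, adjusted p = 0.245). The first and the last of these tested lower.

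In progenitor-like cells, RGC fate transcription factors tested lower (camera adjusted p = 3.10e-10; adjusted p = 0.21 with an estimated correlation; median log2 fold change -0.28), with 9 of 25 lower adjusted over the list alone. They included Pou4f2, a POU factor of RGC differentiation, at 24.4 and 22.0 CPM in WT and 9.75 and 11.9 in RE_KO (log2 fold change -1.09, SE 0.14, n = 2 libraries each), Isl1 (-0.69, SE 0.10), Ebf1 (-0.77, SE 0.13) and Eya2 (-0.89, SE 0.17). Free RNA from RGC-like cells, whose share of neural retinal cells fell from 37.4% to 21.2%, was not measured for RGC genes here. Lower expression within progenitor-like cells therefore cannot be told apart from less free RNA. Neurogenic progenitor genes tested higher (camera adjusted p = 3.31e-11; adjusted p = 0.21 with an estimated correlation; 10 of 22 higher adjusted over the list alone). Neurog2 stood at 106 and 109 CPM in WT and 176 and 182 in RE_KO (log2 fold change 0.73, SE 0.12), with Penk (0.75, SE 0.12), the Notch ligand gene Dll3 (0.65, SE 0.12) and Sstr2 (0.72, SE 0.15). Amacrine and horizontal genes tested higher (camera adjusted p = 3.35e-09; adjusted p = 0.324 with an estimated correlation; 6 of 17 higher adjusted over the list alone), led by Lhx9 (1.40, SE 0.32) and the AP-2 factors Tfap2c (1.23, SE 0.25), Tfap2b (1.09, SE 0.22) and Tfap2a (1.08, SE 0.25).

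No single gene passed in progenitor-like cells: edgeR called 0 of 13934, with 967 at an unadjusted p under 0.05, and DESeq2 called 16. Without RE_KO replicate 1 the edgeR count was 2841, and without RE_KO replicate 2 it was 274. Different clusters make up this class in RE_KO replicate 2 (c1 and c4, above), whose histone genes stood apart. Camera called 10 of 19 lists here, 7 higher and 3 lower, of which 0 held with an estimated correlation and 2 remained without RE_KO replicate 1. In that fit the amacrine and horizontal list no longer passed (adjusted p = 0.0613). The other called lists were axon growth, lower (adjusted p = 8.37e-05), RGC synapse, lower (0.0142), cone and rod precursors, higher (8.37e-05), p53, higher (0.0376), erythroid, higher (0.00115), pigment epithelium and lens, higher (0.00388), and progenitor maintenance and Notch, higher (0.00877). The last had a median log2 fold change of -0.0015 and a mean of 0.13, and the microglia list, not called, tested higher with a median of -0.13 and a mean of -0.19. For these 7 calls, adjusted p ran from 0.21 to 0.471 with an estimated correlation. The erythroid list and the pigment epithelium and lens list hold markers of other cell types. Free RNA was not measured for them, so their rise cannot be read as expression in progenitor-like cells. Lens-like cells made up 1.90% of kept cells in RE_KO replicate 1, 0.429% in RE_KO replicate 2, and 0.247% and 0 in WT.

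In neurogenic-progenitor-like cells, the class in which Atoh7 is normally on, RGC fate transcription factors again tested lower (camera adjusted p = 8.91e-09; adjusted p = 0.486 with an estimated correlation; 5 of 24 lower adjusted over the list alone). Eya2 measured 94.8 and 110 CPM in WT and 44.9 and 47.2 in RE_KO (log2 fold change -1.15, SE 0.14, n = 2 libraries each), with Isl1 (-0.77, SE 0.16), Pou4f2 (-0.75, SE 0.19) and the homeobox gene Dlx1 (-0.53, SE 0.13). As in progenitor-like cells, free RNA from RGC-like cells was not measured for RGC genes. Neurogenic progenitor genes tested higher (camera adjusted p = 0.00275; adjusted p = 0.486 with an estimated correlation), with 6 higher and 1 lower of 23 adjusted over the list alone. Neurog2 (0.67, SE 0.18), Dll3 (0.63, SE 0.18) and Sstr2 (0.66, SE 0.13) were above WT and Rgs16 (-0.55, SE 0.13) below. The amacrine and horizontal list tested higher (camera adjusted p = 2.41e-05; adjusted p = 0.486 with an estimated correlation; 4 of 17 higher adjusted over the list alone), with Slc32a1 (2.34, SE 0.36), Tfap2c (1.72, SE 0.28), Tfap2b (0.93, SE 0.19) and Prdm13 (0.51, SE 0.13). Slc32a1 measured 1.08 and 2.49 CPM in WT, where the libraries differed, and 8.41 and 9.91 in RE_KO. Genes next to Atoh7 on chromosome 10 tested lower (camera adjusted p = 0.0106; adjusted p = 0.486 with an estimated correlation; 1 of 13 lower adjusted over the list alone), with Hnrnph3 (-0.54, SE 0.17), Pbld1 (-2.35, SE 0.51) and Sirt1 (-0.36, SE 0.12) below WT and Dnajc12 (0.57, SE 0.18) above. Pbld1 was low throughout, at 2.93 and 3.08 CPM in WT and 0.89 and 0.30 in RE_KO, where the libraries differed.

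The edgeR test called 0 of 12577 genes in this class, with 1000 at an unadjusted p under 0.05, and DESeq2 called 20. The count was 3 without WT replicate 1, 2029 without RE_KO replicate 1 and 228 without RE_KO replicate 2. Of 19 lists 8 were called, 5 higher and 3 lower, 0 with an estimated correlation and 1 by fry, the neurogenic progenitor list. Without RE_KO replicate 1 there were 4 calls, and the amacrine and horizontal list was not among them (adjusted p = 0.105). The Atoh7-neighbour list no longer passed without RE_KO replicate 2 (adjusted p = 0.0817). The remaining calls were axon growth, lower (adjusted p = 0.0106), and the erythroid (0.00713), microglia (0.0444) and pigment epithelium and lens (0.00184) lists, higher, with adjusted p of 0.486 to 0.539 with an estimated correlation. The lists that rose here hold markers of other cell types, for which free RNA was not measured. The G2 and M phase list (median -0.017, mean 0.023) and the cone and rod list (median -0.072, mean 0.12) had signs that differed and were not called.

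In RGC-like cells, where the question was how the ganglion cells that still form differ, Robo3 rose 25.5-fold, from 1.81 and 1.54 CPM in WT to 43.7 and 42.1 in RE_KO (log2 fold change 4.67, SE 0.15, adjusted p = 1.98e-04, n = 2 libraries each). Genes of the progenitor state rose with it: the Notch effector Hes5 (log2 fold change 1.37, SE 0.16), the progenitor homeobox gene Vsx2 (1.21, SE 0.13) and the helix-loop-helix inhibitor Id1 (1.01, SE 0.11). Carbonic anhydrase 2 (Car2) also rose, from 19.6 and 20.02 CPM to 47.9 and 47.8 (1.27, SE 0.11, adjusted p = 0.0175). Igfbp5, which encodes an insulin-like growth factor binding protein, fell 4.36-fold, from 111 and 97.4 CPM to 26.2 and 21.8 (-2.13, SE 0.15, adjusted p = 0.00638). The netrin receptor Dcc, by which RGC axons leave the eye, fell from 143 and 149 CPM to 68.6 and 71.8 (-1.06, SE 0.12). Ccer2 (-1.67, SE 0.18) and the neuronal helix-loop-helix gene Nhlh1 (-1.13, SE 0.14) fell as well.

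**Figure D3:**
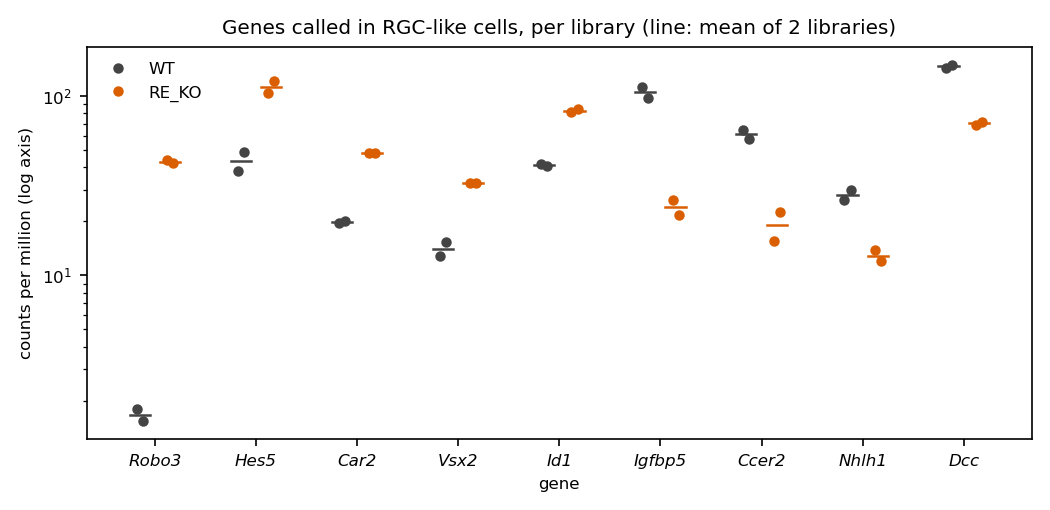
Level (CPM, log axis) of the genes named from the RGC-like fit, Atoh7 aside, in each library. Dots are libraries and lines are means of 2 libraries. Robo3 lies at 1.81 and 1.54 CPM in WT and 43.7 and 42.1 in RE_KO.

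The test called 25 of 14522 genes in RGC-like cells, 14 higher and 11 lower, Atoh7 included. Unadjusted, 1518 had a p under 0.05, and DESeq2 called 135, with all 25 among them. Leaving out WT replicate 1, WT replicate 2, RE_KO replicate 1 or RE_KO replicate 2 gave 120, 143, 3066 and 697, each holding the 25. At equal depth 13 remained, with no doublets removed 14 remained, and Hes5, Vsx2, Id1, Ccer2, Nhlh1 and Dcc were among those lost in each case (adjusted p 0.06 to 0.178), while Robo3, Igfbp5, Car2 and Atoh7 kept their calls there.

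Progenitor maintenance and Notch genes tested higher in RGC-like cells (camera adjusted p = 6.77e-19; adjusted p = 0.245 with an estimated correlation; median log2 fold change 0.67). Adjusted over the list alone, 15 of 24 were higher and 1 lower, while over all genes 3 passed, namely Hes5, Vsx2 and Id1; Lhx2 measured 0.93 (SE 0.14, adjusted p = 0.0723). Cell cycle lists moved the same way, S phase (camera adjusted p = 2.61e-10; adjusted p = 0.283 with an estimated correlation; 10 of 20 higher adjusted over the list alone) and G2 and M phase (4.21e-16; adjusted p = 0.286 with an estimated correlation; 9 of 22). The replication helicase genes Mcm3 (0.87, SE 0.15), Mcm4 (0.66, SE 0.13) and Mcm5 (0.77, SE 0.16), with E2f8 (0.85, SE 0.23), led the first. The mitotic genes Birc5 (0.97, SE 0.13), Cdk1 (0.84, SE 0.12), Aurkb (0.93, SE 0.13) and Ube2c (0.67, SE 0.13) led the second, with 0 members passing over all genes in either. Beside these lists stands a measure of free RNA: 9 progenitor-list genes that non-neural cells lack summed to 320 and 469 CPM in WT and 513 and 891 in RE_KO within erythroid-like and microglia/macrophage-like cells, and to 366 and 385, then 672 and 545, within RGC-like cells.

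Amacrine and horizontal genes tested higher in RGC-like cells (camera adjusted p = 7.44e-16; adjusted p = 0.245 with an estimated correlation; median 0.87), with 10 higher and 1 lower of 21 adjusted over the list alone. Slc32a1, the vesicular GABA transporter, passed over all genes, from 1.85 and 1.90 CPM to 5.69 and 6.01 (log2 fold change 1.64, SE 0.20, adjusted p = 0.0473, chosen as a list member). The factors Tfap2b (1.89, SE 0.24), Tfap2a (1.64, SE 0.24) and Prdm13 (0.93, SE 0.16) did not pass over all genes. RGC fate transcription factors tested lower (camera adjusted p = 9.75e-05; adjusted p = 0.245 with an estimated correlation), with 6 of 26 lower adjusted over the list alone and 0 over all genes: Ebf2 (-1.48, SE 0.19), Eya2 (-0.87, SE 0.14), Tshz2 (-0.61, SE 0.12) and Irx6 (-0.46, SE 0.11). Axon growth and guidance genes tested lower (camera adjusted p = 0.00216; adjusted p = 0.245 with an estimated correlation), with 5 lower and 1 higher of 41 adjusted over the list alone. Dcc passed over all genes, while the adhesion molecule Alcam (-1.30, SE 0.18), Robo1 (-0.53, SE 0.12) and Dscam (-0.45, SE 0.11) did not. Without RE_KO replicate 1 the axon list did not pass (adjusted p = 0.0616).

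Of the 19 lists 12 were called in RGC-like cells, 9 higher and 3 lower, 0 with an estimated correlation and 1, axon growth, by fry in one direction. The other calls were neurogenic progenitor (adjusted p = 4.05e-04), cone and rod precursor (0.00334), p53 (0.0339), dissociation stress (0.00583) and vascular (9.75e-05) genes, higher, and erythroid genes, lower (0.00803), whose adjusted p ran from 0.245 to 0.525 with an estimated correlation. Free RNA was not measured for the vascular and erythroid lists, which hold markers of other cell types. The optic stalk list, not called, tested lower with a median of 0.0050 and a mean of -0.051.

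Photoreceptor-precursor-like cells shared the lower Igfbp5: it fell from 118 and 132 CPM to 47.0 and 50 (log2 fold change -1.36, SE 0.16, adjusted p = 0.0197, n = 2 libraries each). With Atoh7 it made 2 calls of 11132 genes tested, with 768 at an unadjusted p under 0.05 and 2 by DESeq2. The Igfbp5 call was lost without WT replicate 2 (-1.27, adjusted p = 0.163), the count being then 1, and under 5 other settings, down to -0.82 at the stricter cell filter. The count was 10 without WT replicate 1, 1332 without RE_KO replicate 1 and 100 without RE_KO replicate 2. In amacrine/horizontal-like cells Atoh7 was the 1 call of 11132, with 702 at an unadjusted p under 0.05 and 2 by DESeq2. Igfbp5 measured 247 and 299 CPM there in WT and 287 and 206 in RE_KO (log2 fold change -0.15, SE 0.20, adjusted p = 0.901). Without WT replicate 1, WT replicate 2, RE_KO replicate 1 and RE_KO replicate 2 that class gave 12, 2, 1001 and 57 calls.

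Whether the genotype acted differently in RGC-like than in progenitor-like cells was tested directly. Robo3 rose more in RGC-like cells (difference in log2 fold change 2.23, SE 0.50, adjusted p = 0.00656, n = 2 libraries each), and the difference for Atoh7 was -1.37 (SE 0.08, adjusted p = 6.08e-11). Atoh7 in RE_KO RGC-like cells, at 38.8 and 36.6 CPM, lay at the free-RNA level of 29.6 and 76.1. Such a floor limits the fall that can be measured there, and free RNA was not subtracted in either class. The difference is therefore one between droplets, and whether expression fell more in RGC-like cells stays open. The tubulin gene Tuba1c had 4.27 and 5.21 CPM in WT and 10.0 and 9.48 in RE_KO RGC-like cells, but 39.4 and 43.4, then 29.3 and 26.1, in progenitor-like cells (difference 1.63, SE 0.15). Greb1 (1.40, SE 0.13) and the histone gene Hist1h3a (1.43, SE 0.24) also differed upwards. Hist1h3a is among the transcripts that set RE_KO replicate 2 apart, at 8.86 CPM in its progenitor-like cells against 34.4 to 36.1 in the other libraries. The protocadherin Pcdh10 (-1.20, SE 0.17), Frrs1l (-0.96, SE 0.16) and the cell cycle inhibitor Cdkn1a (-0.93, SE 0.15) differed downwards.

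This model called 560 of 14964 genes, 426 with a higher and 134 with a lower effect in RGC-like cells, with 2107 at an unadjusted p under 0.05 and 202 by DESeq2, of which 197 were shared. Without WT replicate 1 it called 335, and Robo3 was not among them (difference 2.06, adjusted p = 0.202). The difference for Atoh7 was not called with no doublets removed (adjusted p = 0.097), at Leiden resolution 2 (0.366) or with cells over 25000 UMIs left out (0.411).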

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

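The test of the rise across UMI ranges and the removal of each library from the tests of the first pattern below were chosen after the results they measure were seen, as were the patterns themselves.

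A difference in genotype effect between RGC-like and progenitor-like cells set 560 genes apart, by the interaction test given above. Those named were Robo3 (difference in log2 fold change 2.23), Tuba1c (1.63), Hist1h3a (1.43), Greb1 (1.40), Atoh7 (-1.37), Pcdh10 (-1.20), Frrs1l (-0.96) and Cdkn1a (-0.93).

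Other signals lay in cells outside the compared classes, above both WT libraries in 1 RE_KO library or in both. Microglia/macrophage-like cells made up 3.27% of kept cells in RE_KO replicate 1 (95% interval 2.84 to 3.74) and 2.07% in RE_KO replicate 2, against 1.68% and 1.56% in WT, and 124 and 109 of the RE_KO cells lie in cluster c0, whose leading genes include the neutrophil genes S100a9, S100a8, Ngp and Camp. Lens-like cells made up 1.90% and 0.429% of the RE_KO libraries, against 0.247% and 0 in WT. The unnamed cluster c17, led by the lens crystallin genes Crygb, Cryga and Crygd, held 7.36% of RE_KO replicate 1 but 0.505% of RE_KO replicate 2, against 2.88% and 1.21% in WT. Cluster c9, with the photoreceptor genes Crx, Prdm1, Thrb and Pdc among its leading genes, held 5.36% of RE_KO replicate 1 and 12.3% of RE_KO replicate 2, against 3.92% and 3.34% in WT. Cluster c14 held 2.67% of RE_KO replicate 1 but 0.707% of RE_KO replicate 2, against 1.10% and 1.12% in WT, and cluster c21 held 2.01% of RE_KO replicate 2 but 0.0635% of RE_KO replicate 1, against 0.0329% and 0.0499% in WT. Median depth was 30276 UMIs in c9, 52206 in c14 and 24080 in c21, or 4.50, 7.45 and 3.58 times the library median. The marker scores of c9 were 0.81 for progenitor-like and 0.74 for photoreceptor-precursor-like cells. Mixed droplets were not excluded in these clusters, so their shares cannot be read as those of 1 cell type.

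Progenitor and cell cycle genes were higher in RGC-like cells of RE_KO, with a median log2 fold change of 0.54 over 66 genes of 3 lists. A change in the mix of RGC clusters as the whole cause was argued against, since the median was 0.41 within c2 and 0.84 within c3, the smaller being 0.771 of that of the whole class (95% interval 0.635 to 0.885; 0.715 to 0.806 with each library left out). A part of the rise from the mix is not excluded by these values. Free RNA from progenitors as the whole cause was argued against too: droplets taking up equal numbers of free UMIs would show a smaller rise in CPM at greater depth, but the rise was 1.59 times as large (1.44 to 1.77) at 20000 to 40000 UMIs (302 CPM) as at 10000 to 20000 (190 CPM), or 1.12 without RE_KO replicate 1 and 2.24 without RE_KO replicate 2. Free RNA as part of the cause cannot be told apart from the rest, because the rise of 9 progenitor genes in non-neural cells was 1.32 times that in RGC-like cells (308 and 233 CPM) but 0.401 times without RE_KO replicate 2 and 2.94 times without RE_KO replicate 1. Droplets that mix an RGC and a progenitor, and a partial retention of the progenitor state in ganglion cells, which was not tested itself, also stay open: the median was -0.07 below the library's median UMI count and 0.73 above it (ratio -0.0986), but the ratio was 0.509 without WT replicate 2 and -0.629 without WT replicate 1, and without the low-UMI cluster c11 it was 0.371 (0.27 and 0.72; 0.287 to 0.547 with each library left out).

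RE_KO replicate 2 stood apart from the other 3 libraries by low replication-dependent histone transcripts, with a median log2 ratio of -1.81 in progenitor-like, -1.54 in neurogenic-progenitor-like, -0.84 in RGC-like, -1.35 in photoreceptor-precursor-like and -1.45 in amacrine/horizontal-like cells. In RGC-like cells it was not alone: RE_KO replicate 1 lay at 0.87 over its other libraries, against -0.12 and -0.05 in WT. In amacrine/horizontal-like cells RE_KO replicate 1 lay at 0.78. Fewer cells in S phase were argued against, because the S phase list had a median log2 ratio of 0.0034 in progenitor-like cells (95% interval -0.06 to 0.10), with 10 of 20 genes lower, while 58 of 61 histone genes were lower. A lower capture of RNA without a poly(A) tail cannot be told apart from other causes, since 3 ribosomal-repeat transcripts gave a median of -0.22 (Gm42418 -0.61, Gm26917 -0.22, AY036118 -0.10), too few to decide. No biological explanation other than the share of cells in S phase was tested, as the labels give RE_KO replicate 2 nothing that sets it apart from RE_KO replicate 1.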

How the results depend on the processing

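Leaving out cells over 25000 UMIs, clustering without the genes called in any class, crossing the pairs and not thinning were alternatives chosen after seeing the data. For 132 genes and lists named in the text, 1472 of 1905 comparisons kept direction and side of the threshold, 115 lost the threshold, 316 gained it and 2 reversed. The 2 were the pigment epithelium and lens list and Mip over all cells, each at -0.11 without RE_KO replicate 1, with 1 library left out ranging from -0.11 to 3.94 for the list and -0.11 to 6.04 for Mip. For the 19 results that answer a comparison, 143 of 268 comparisons kept both, or a count within 1.5 times; 19 lost the threshold, 13 gained it, 8 reversed and 85 moved. Where nothing else is said, the cause was not tested.

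With 1 library left out, the lone library is assumed to vary like the other group, and fewer samples are compared. The ranges were -2.38 to -2.22 for Atoh7 over all cells, -2.57 to -2.34 for Atoh7 in neurogenic-progenitor-like cells, 0.45 to 0.58 for the progenitor-like share, -0.94 to -0.71 for the RGC-like share and 0.40 to 0.63 for the photoreceptor-precursor-like share. The neurogenic-progenitor-like share ranged from -0.037 to 0.068 (reversed without WT replicate 1, -0.0025, and without RE_KO replicate 1, -0.037) and the amacrine/horizontal-like share from -0.15 to 0.38 (reversed without WT replicate 2, -0.15, and without RE_KO replicate 1, -0.0084). Counts of genes ranged from 0 to 4711 in all cells, 0 to 2841 in progenitor-like, 0 to 2029 in neurogenic-progenitor-like, 120 to 3066 in RGC-like, 1 to 1332 in photoreceptor-precursor-like and 2 to 1001 in amacrine/horizontal-like cells, and from 335 to 621 for the difference between classes. Without RE_KO replicate 1 the edgeR counts were the highest in every class and in all cells. Counts of lists ranged from 11 to 12 in all cells, 2 to 10 in progenitor-like, 4 to 9 in neurogenic-progenitor-like and 8 to 14 in RGC-like cells.

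DESeq2 gave -2.30 for Atoh7 over all cells (adjusted p = 1.34e-46), -2.45 in neurogenic-progenitor-like cells (2.78e-29), and 504 genes in all cells, 16 in progenitor-like, 20 in neurogenic-progenitor-like, 135 in RGC-like and 2 in amacrine/horizontal-like cells, with 202 for the difference between classes. Without a filter on low counts, Atoh7 was at -2.31 over all cells (0.0012) and -2.46 in neurogenic-progenitor-like cells (9.82e-10), and the counts were 263, 57, 128, 325, 59 and 50 over all cells and in progenitor-like, neurogenic-progenitor-like, RGC-like, photoreceptor-precursor-like and amacrine/horizontal-like cells. Without TMM, counts were 3 in neurogenic-progenitor-like, 59 in RGC-like, 4 in photoreceptor-precursor-like and 2 in amacrine/horizontal-like cells. At equal depth they were 3 in neurogenic-progenitor-like and 13 in RGC-like cells, with Atoh7 at -2.45 in neurogenic-progenitor-like cells (0.0373). Camera with an estimated correlation called 0 lists in all cells and in the 3 classes, and fry in one direction 0, 0, 1 and 1. Shares without thinning gave 74.6% of neurogenic-progenitor-like cells of RE_KO with an Atoh7 UMI, since more UMIs per cell are read.

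With replicate number as a replicate block, Atoh7 was at -2.31 over all cells (adjusted p = 0.0223) and -2.46 in neurogenic-progenitor-like cells (0.0451), and the counts were 89 in all cells, 21 in progenitor-like, 24 in neurogenic-progenitor-like, 60 in RGC-like, 11 in photoreceptor-precursor-like and 9 in amacrine/horizontal-like cells. The labels give no sign that equal numbers share a litter or day, and the deviations of same-numbered libraries correlated at -0.0293 over all cells and -0.234 in RGC-like cells, so the pairing was not used. Crossing the pairs gave 159 genes in all cells, 37 in neurogenic-progenitor-like, 160 in RGC-like and 30 in amacrine/horizontal-like cells.

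With the stricter cell filter, counts were 2 in all cells, 74 in RGC-like and 5 in photoreceptor-precursor-like cells and 968 for the difference, the neurogenic-progenitor-like share was -0.10 and the photoreceptor-precursor-like share 0.056. With no doublets removed, counts were 1 in all cells, 1 in neurogenic-progenitor-like, 14 in RGC-like, 1 in photoreceptor-precursor-like and 2 in amacrine/horizontal-like cells and 339 for the difference, and the photoreceptor-precursor-like share was 0.37. With cells over 25000 UMIs left out, counts were 0 in all cells, 4 in neurogenic-progenitor-like, 1 in photoreceptor-precursor-like and 3 in amacrine/horizontal-like cells and 255 for the difference, Atoh7 in neurogenic-progenitor-like cells was at -2.47 (adjusted p = 0.0391), the neurogenic-progenitor-like share at -0.014 and the photoreceptor-precursor-like share at 0.46.

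With libraries clustered alone, the shares were 0.22 (progenitor-like), -0.75 (RGC-like) and 0.80 (photoreceptor-precursor-like). Atoh7 was then at -2.68 in neurogenic-progenitor-like cells (adjusted p = 0.0472), counts were 3 in neurogenic-progenitor-like, 13 in RGC-like and 1 in photoreceptor-precursor-like cells and 261 for the difference, and 14 lists were called in neurogenic-progenitor-like cells. With all cells as denominator the same 3 shares were 0.73, -0.57 and 0.74, with the unnamed cells counted in. List genes kept in the clustering gave a photoreceptor-precursor-like share of 0.14, and TMM over classes a neurogenic-progenitor-like share of -0.037. Clustering without the genes called in any class gave a neurogenic-progenitor-like share of -0.15 and counts of 3 in neurogenic-progenitor-like, 40 in RGC-like, 1 in photoreceptor-precursor-like and 0 in amacrine/horizontal-like cells (edgeR), where Atoh7 then had adjusted p = 0.101. Leiden resolution 2 kept each of the 15 results that answer a comparison, while of 81 named genes and lists 75 kept theirs, 5 lost the threshold and 1 gained it.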

Other observations

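The test of a chromosome segment and that of a genetic background were run on genes picked from the results, and the cluster values in this part were chosen after the data were seen.

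Among the RGC-like clusters, Atoh7 was highest in c3 in WT (959 and 982 CPM, against 96.2 and 133 in c2, 204 and 402 in c11 and 119 and 146 in c18). Robo3 measured 4.34 and 3.38 CPM in c3 of WT and 122 and 118 in RE_KO, and 0.65 and 0.82, then 7.48 and 10.4, in c2. Igfbp5 measured 265 and 243 CPM in c3 of WT and 40.9 and 41.7 in RE_KO. Dcc went from 313 and 334 CPM to 120 and 142 in c3 and from 47.6 and 57.9 to 35.2 and 36.2 in c2. Nhlh1 went from 67.6 and 82.5 CPM to 32.8 and 29.7 in c3, and Ccer2 from 151 and 147 to 34.3 and 46.2. Other clusters moved too: the log2 ratio was 4.96 for Robo3 in c3 and 4.73 in c18, 1.69 for Car2 in c3 and 2.36 in c18, and -2.62 for Igfbp5 in c3, -2.56 in c11 and -0.07 in c18. The ratios outside c3 rest on few UMIs. In c18, Robo3 had 0 and 1 in WT and 7 and 16 in RE_KO, and Car2 had 6 and 4, then 12 and 28. Igfbp5 in c11 had 18 and 161 in WT and 3 and 5 in RE_KO. Whether the effect differed between these clusters was not tested. Gfi1, a zinc-finger gene outside the naming rule and chosen after its values were seen, measured 2.70 and 2.65 CPM in RGC-like cells of WT and 15.7 and 13.2 in RE_KO (log2 fold change 2.42).

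Igfbp5 was below WT in neurogenic-progenitor-like cells as well, at 231 and 250 CPM in WT and 77.5 and 78.4 in RE_KO (log2 fold change -1.63, adjusted p = 0.0515 by edgeR), without passing the threshold. Robo3 measured 0.57 and 0.41 CPM in progenitor-like cells of WT and 2.38 and 2.90 in RE_KO (log2 fold change 2.43, adjusted p = 0.376 by edgeR). In photoreceptor-precursor-like cells it measured 3.12 and 4, then 4.99 and 4.63 (0.41, adjusted p = 0.874). Cluster c23, unnamed, held Pax2 at 579 CPM against 1.30 in other cells. It took in 0.494% ± 0.0235 of kept cells in WT (29 and 41 cells) and 0.136% ± 0.0576 in RE_KO (6 and 14 cells, n = 2 libraries each).

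Besides Atoh7, 11 genes were changed at least 2-fold in the same direction in every fit that tested them, counting genes tested in at least 4 fits with both RE_KO libraries on the same side of both WT libraries over all cells, among them Gng4, Ccdc7a, Hddc3, Hes2, Fggy and Grm2. A chromosome segment carried along around Atoh7 was argued against as the source of these 11 genes alone, since 0% of them (0 of 11) lie within 20 Mb of it, where 2.10% of the tested genes lie (exact one-sided binomial p = 1). With so few genes, that outcome is also the usual one without a segment. Changes that are smaller or bound to 1 class are not covered, such as the Atoh7-neighbour list in neurogenic-progenitor-like cells (lower, camera adjusted p = 0.0106; 0.486 with an estimated correlation). A genetic background that differs between the genotypes and acts in all cells could not be decided: 70% of the genes with at least 10 UMIs in non-neural cells (7 of 10) differed at least 2-fold the same way there, which free RNA could bring about too. Hddc3, for example, had 25 and 20 UMIs in non-neural cells of WT and 51 and 81 in RE_KO.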
